A study of Ictidomys tridecemlineatus with 6 samples.

How the data were processed

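RNA was measured in crushed optic nerves of Ictidomys tridecemlineatus, a ground squirrel that hibernates, 3 days after the crush. There were 6 libraries, 3 from hibernating and 3 from awake animals. Per the labels' protocols, total RNA was isolated from tissue lysed in TRIzol and purified with a miRNeasy kit, and libraries were made with a stranded mRNA kit. Per the series' design text, sequencing was paired-end. The protocols do not state that each library came from a separate animal, so the p-values measure the spread between these libraries, part of which may be technical.

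The authors deposited 1 file of counts per library, with whole-number read counts for 22398 Ensembl gene identifiers and no header. The counts are not normalised, and the files hold no row for reads outside genes. The submitters' processing notes name bcl2fastq 2.19.1, cutadapt 1.8.1, TopHat2 2.1.1 and featureCounts 1.6.0. The deposited files are named as HTSeq counts, so which of these counters made the values is not clear. The genome build, the annotation release and the strand setting are not given in the sources used here. Without the strand setting, it is not known how reads of overlapping and antisense genes were counted. Apart from strand, counts of near-identical paralogs may be unreliable, since their reads can match more than 1 gene.

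The deposited files do not pair the identifiers with gene names. A RefSeq gene table of the species with 42748 genes was available, but it gives an Ensembl identifier for 0 of them, so none of the 22398 identifiers could be looked up in it and no gene is named here. This is a limit of the table and says nothing about the identifiers. The 43 lists of cell type markers and processes and the panel of 14 genes, fixed by symbol before the data were examined, were not tested. Gene positions, GC content and gene length were not used here.

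Counts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM normalisation and the hibernating and awake groups as the only term. The default filterByExpr filter (minimum count 10) left 13850 genes that held 99.9% of all counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are hibernating over awake, and their standard errors were derived from the F statistic. CPM values are TMM-normalised counts scaled to a common library size of 1000000, and log2 CPM values used a prior count of 2. Tested genes were divided by their mean CPM over the 6 libraries into 4 abundance classes of equal size, from class 1 (lowest) to class 4 (highest). Library measures were compared with two-sided exact permutation tests. With 3 libraries against 3, such a test cannot give a p below 0.1.

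The genes to be named were fixed by a rule before the data were examined. It took the largest fold changes in each direction among called genes with a symbol, with no overlap between the groups' libraries and a mean of at least 5 CPM in the higher group. As no gene had a symbol, that condition was dropped and the identifiers of only the first 2 genes in each direction are given, out of 123 higher and 295 lower genes that met the rest of the rule. Identifiers of other genes are not printed.

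The test was checked on simulated data for the same comparison, with counts drawn for the 13850 tested genes from the libraries' own means, sizes and dispersions and 200 genes changed. It recovered 23.9% of 67 genes changed 2-fold, 68.7% of 67 genes changed 4-fold and 95.5% of 66 genes changed 8-fold. It also called 9 unchanged genes. The simulation gave both groups the same dispersion and let genes vary independently, unlike the real libraries, so these rates may not carry over. Library totals lay between 16337406 and 19256370 counts. The median standard error of a log2 fold change was 0.30 over all tested genes.

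Alternatives fixed in advance were other scalings (DESeq2 size factors, upper quartile, library totals), no filter and a stricter filter, a replicate block, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust dispersions, other thresholds, and leaving out each library. Library weights, a loess correction for abundance and removal of a set of genes shared by 2 libraries were added after seeing the data. The correction for GC content and gene length could not be made.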

Results

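The study compared the RNA of crushed optic nerves between hibernating and awake ground squirrels 3 days after the injury. Optic nerve crush is a standard injury that severs the axons of retinal ganglion cells while leaving the nerve sheath in place. Each group had 3 libraries. Uncrushed nerves were not analysed here, so the comparison gives the difference between the states after injury and not the response to injury within either state. Because no table at hand paired the identifiers with gene names, genes are described in groups defined by direction, size of change and abundance.

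The hibernating libraries held 19124136, 16337406 and 17598207 counts in replicates 1, 2 and 3, and the awake libraries held 17062092, 19256370 and 18509562. Totals did not differ between the groups by more than the spread of their libraries (two-sided exact permutation test, n = 3 each, p = 0.6). Between 15778 and 17059 genes had at least 1 count per library. The most abundant gene took 1.95% to 3.72% of a library's counts, and the 10 most abundant genes together took 9.49% to 10.8%. No library was a repeat of another. Counts of the most similar pair of the same group, awake replicates 1 and 2, still differed with a chi-square of 32.4 per degree of freedom.

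The hibernating libraries had more detected genes than the awake libraries and a smaller share of counts in the 1000 most abundant genes, in 3 of 3 libraries each, but with 3 libraries per group neither difference could pass a test. Genes with 10 or more counts numbered 13967 ± 529 in the hibernating and 13445 ± 122 in the awake libraries (SD, n = 3 each). The 1000 most abundant genes held 62.1% ± 3.27 of the counts in the hibernating and 66.1% ± 1.101 in the awake libraries. For both measures every hibernating library lay on the same side of every awake library, which gives the smallest two-sided exact permutation p the design allows (p = 0.1; adjusted p = 0.175 over 7 library measures). The median count per gene (52.3 ± 20.5 in hibernating, 35.7 ± 3.51 in awake) and the TMM factor (1.11 ± 0.155 and 0.906 ± 0.0529) separated the groups likewise. The scaling thus differed with state, and without it, with library totals only, 11 genes were called. The shares of the 10 and of the 100 most abundant genes overlapped between the groups, at 10.3% ± 0.548 and 28.1% ± 2.26 in the hibernating and 10.02% ± 0.459 and 29.5% ± 0.245 in the awake libraries (SD, n = 3 each; two-sided exact permutation tests, p = 0.5 and p = 0.4). Hibernating replicate 1 stood apart from the rest, with 14574 such genes and 58.4% of its counts in the top 1000.

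The awake libraries resembled each other more than the hibernating libraries did. Across the 13850 tested genes, Pearson correlations of log2 CPM lay between 0.967 and 0.976 for the 3 awake pairs and between 0.942 and 0.949 for the 3 hibernating pairs. Pairs across the groups gave 0.899 to 0.950, and 3 of them lay slightly above the highest hibernating pair (0.9494). These were hibernating replicate 3 with awake replicates 1 and 2 (0.9503 and 0.9505) and hibernating replicate 2 with awake replicate 1 (0.9500). These correlations are across genes, which are not independent replicates. The first principal component, with 49.0% of the variance, separated the groups, and the second, with 17.7%, set hibernating replicate 3 apart. Scores on the first ran from -69.7 to -19.8 in the hibernating and from 20.1 to 67.2 in the awake libraries. The gap between the groups was thus smaller than the range within either. The order of the libraries was that of their TMM factors, but for hibernating replicates 2 and 3. The component therefore does not tell state from library composition.

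**Figure D1:**
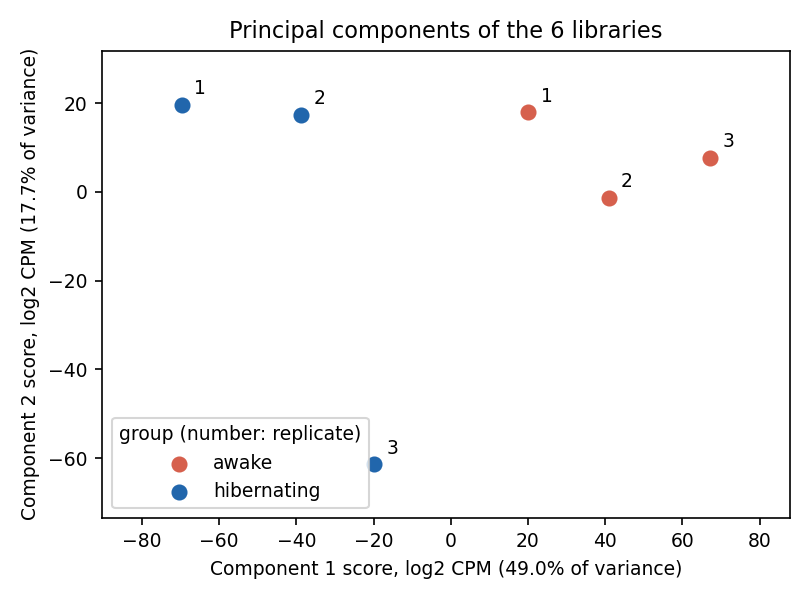
Scores of the 6 libraries on the first principal component (x axis, 49.0% of variance) and the second (y axis, 17.7%) of log2 CPM over 13850 genes. Each point is 1 library, coloured by group and numbered by replicate; the hibernating libraries lie at negative and the awake libraries at positive scores of the first component, and hibernating replicate 3 lies alone on the second.

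Between hibernating and awake crushed nerves, 463 of the 13850 tested genes (3.34%) changed. Of these, 310 were lower and 153 were higher in the hibernating nerves. The median log2 fold change was -1.42 among the lower and 1.67 among the higher genes, with a median standard error of 0.26 and 0.32. Among the lower genes, 39 changed by less than 2-fold, 200 by 2- to 4-fold, 49 by 4- to 8-fold and 22 by 8-fold or more. Among the higher genes these numbers were 6, 97, 34 and 16.

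The test was the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and the calls sat close to its threshold. The smallest adjusted p was 0.00111 and was reached by 1 gene that was higher in the hibernating nerves, the only one below 0.01. An unadjusted p under 0.05 was found for 3701 genes (26.7%). With upper-quartile scaling 137 genes were lower and 93 higher, and with library totals only 8 were lower and 3 higher. Leaving out awake replicate 2 or awake replicate 3 reduced the calls to 1 gene each. Without hibernating replicate 1, hibernating replicate 2 or awake replicate 1 there were 135, 170 and 166 calls. The 463 called genes all kept their direction in each of these fits. This was nearly fixed beforehand, since 462 of them had no overlap between the groups' libraries, so leaving 1 out could hardly turn their sign. Upper-quartile scaling and library totals moved the median log2 fold change of all genes to 0.17 and 0.34, against smallest called changes of 0.88 and -0.80.

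All libraries of one group lay above all libraries of the other for 4644 tested genes (33.5%), where chance gives 10% for a single gene. Genes vary together, so the share in a random split may lie far from 10%, and it was not computed for other splits. Of the 4644 genes, 2302 were higher in every hibernating library and 2342 in every awake library. The TMM scaling, which centres the fold changes, largely sets this balance. All 310 lower genes and 152 of the 153 higher genes were among the 4644. The excess of lower genes among the calls depended on hibernating replicate 3. Without it the lower genes stayed near their number, at 301 against 310, but 390 genes were higher against 153.

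The share of lower genes among the calls was largest in the most abundant class. In class 4 of the 4 equal abundance classes, the genes with the highest mean expression (49.4 CPM and above), 125 genes were lower and 11 were higher in the hibernating nerves. In classes 1 to 3 together, 185 were lower and 142 higher, a different split (two-sided Fisher's exact test across genes, which are not independent, p = 3.11e-15). In class 1, the least abundant (up to 3.72 CPM), 18 genes were lower and 31 higher. In class 2 the numbers were 67 and 56, and in class 3 they were 100 and 55. The median standard error fell from 0.50 in class 1 to 0.23 in class 4, so changes in either direction were easier to call in abundant genes. Of the called genes that reached 100 CPM in their higher group, 94 were lower and 6 higher, and the 6 that reached 1000 CPM were all lower in hibernating nerves. Without hibernating replicate 1 the difference between the classes was no longer past the threshold (46 lower and 6 higher in class 4, 66 and 17 in the others; Fisher's exact test, p = 0.241). Nor was it past the threshold after a loess correction for abundance, which removes such a trend by construction (67 lower and 28 higher in class 4, 207 and 72 in the others; p = 0.504 by Fisher's exact test), and with library totals only, without awake replicate 2 or without awake replicate 3 no more than 11 calls were left to compare.

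The same gradient ran through all tested genes. The median log2 fold change was 0.38 in abundance class 1, 0.26 in class 2, 0.03 in class 3 and -0.26 in class 4. The difference between classes 4 and 1 was -0.64, and it stayed between -0.77 and -0.39 when each library was left out, the weakest value being that without hibernating replicate 1. Measured within each library against the mean of all 6, the same contrast was -0.33 ± 0.40 in the hibernating and 0.28 ± 0.15 in the awake libraries (SD, n = 3 each; two-sided exact permutation test, p = 0.1, the smallest possible). Hibernating replicate 1 carried most of the hibernating mean, at -0.79 against -0.09 and -0.10 in replicates 2 and 3.

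**Figure D2:**
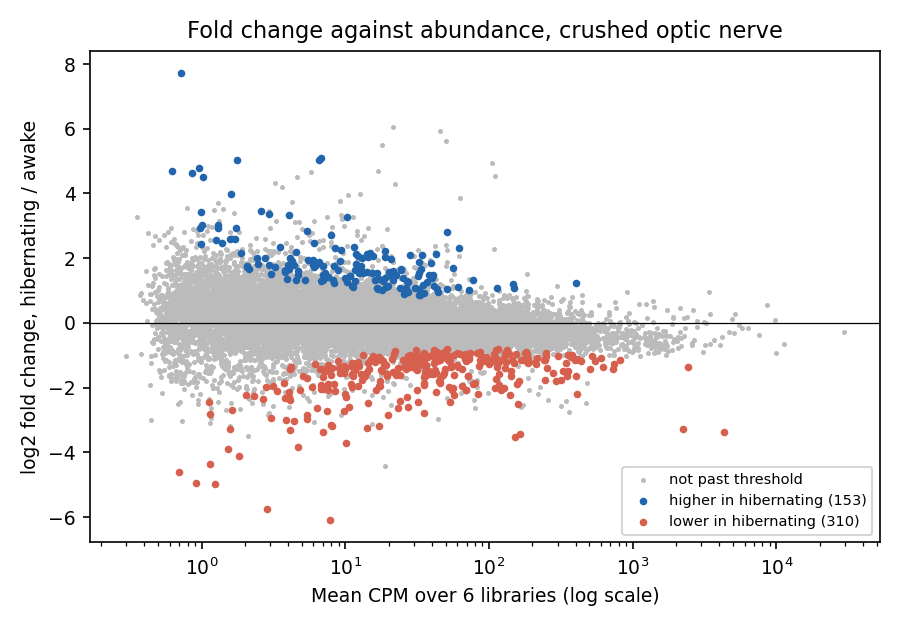
Log2 fold change, hibernating over awake (y axis), against mean CPM over the 6 libraries (x axis, log scale) for the 13850 tested genes, each point 1 gene. Blue points are the 153 genes called higher and red points the 310 called lower in hibernating nerves, grey points the rest; at 1000 CPM and above all called genes are lower.

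The called genes made up a small part of each library. The 310 lower genes held 4.70% ± 0.162 of the tested counts in the awake and 1.88% ± 0.154 in the hibernating libraries (SD, n = 3 each). The 153 higher genes held 0.158% ± 0.0295 in the awake and 0.520% ± 0.137 in the hibernating libraries. Both sets were chosen by the test on these libraries, so the shares describe the sets and are not independent evidence of their direction.

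Among the genes that met the naming rule, ENSSTOG00000026677 had the largest rise in hibernating nerves, with a log2 fold change of 5.08 ± 0.87 (SE; edgeR quasi-likelihood test, adjusted p = 0.0294). Its level was 13.1 ± 10.1 CPM in the hibernating and 0.377 ± 0.165 CPM in the awake libraries (SD, n = 3 each). The hibernating libraries were uneven, at 20.9 and 16.7 CPM in replicates 1 and 2 and 1.71 CPM in replicate 3. It was 1 of 12 genes at least 8-fold higher in hibernating replicates 1 and 2 than in every other library. ENSSTOG00000015991 followed with a log2 fold change of 3.37 ± 0.58 (edgeR adjusted p = 0.0294), from 0.516 ± 0.228 CPM in awake to 5.42 ± 3.55 CPM in hibernating nerves. Without hibernating replicate 1 its log2 fold change was 2.68.

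The largest fall was that of ENSSTOG00000029160, with a log2 fold change of -6.09 ± 1.13 (SE; edgeR adjusted p = 0.0332). It stood at 15.4 ± 16.3 CPM in the awake libraries, of which replicate 2 alone reached 34.1 CPM. In the hibernating libraries it had 14 counts in replicate 1 and 0 in the other two. Its log2 fold change was -4.78 without awake replicate 2. Without hibernating replicate 1 the fitted value was -11.03. That value depends on the fit's own default prior count, not the 2 used for log2 CPM, because both remaining hibernating libraries had 0 counts. ENSSTOG00000011297 fell by 5.75 on the log2 scale, with a standard error of 0.71 (edgeR adjusted p = 0.0161). It stood at 5.61 ± 2.34 CPM in the awake libraries, and the 3 hibernating libraries held 6 counts of it in all against 282 in the awake libraries. Without hibernating replicate 1, which held 5 of those 6 counts, its fitted log2 fold change was -7.28. None of the 4 genes passed the threshold without awake replicate 2 or without awake replicate 3. Without hibernating replicate 1, ENSSTOG00000026677, ENSSTOG00000015991 and ENSSTOG00000029160 also lost it (edgeR adjusted p = 0.0658, 0.0601 and 0.0618). The first 2 of these lost it without awake replicate 1 (edgeR adjusted p = 0.0667 and 0.0618) and ENSSTOG00000029160 without hibernating replicate 2 (edgeR adjusted p = 0.0544). The direction of all 4 held in every alternative, which the naming rule largely fixed by taking large changes with no overlap between the groups' libraries.

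**Figure D3:**
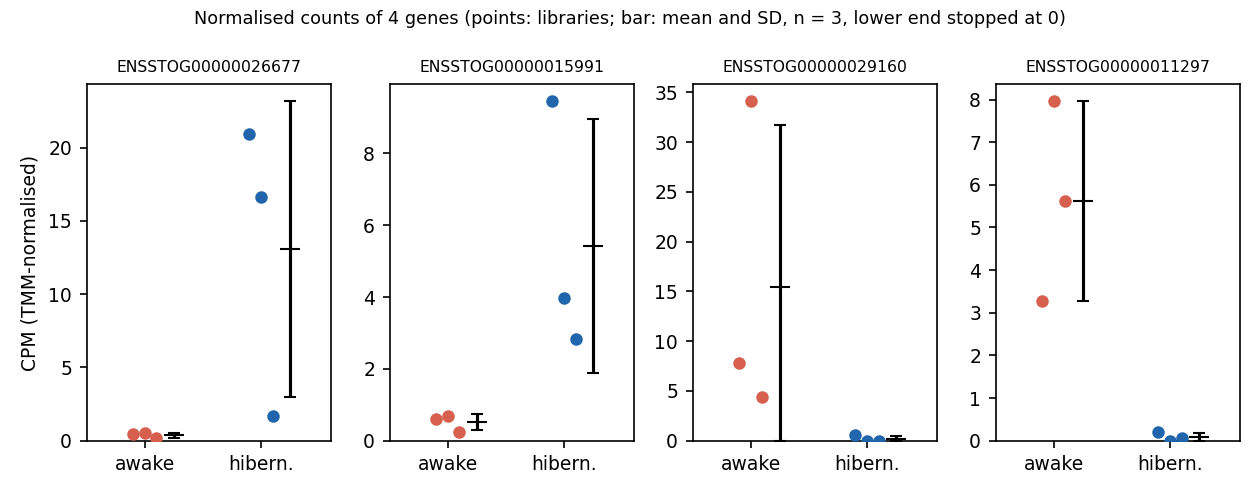
TMM-normalised CPM (y axes, linear from 0) of 4 genes in the awake (red) and hibernating (blue) libraries. Points are single libraries and bars the mean and SD of 3 libraries, with the lower end stopped at 0; ENSSTOG00000026677 and ENSSTOG00000015991 are higher in every hibernating library, and ENSSTOG00000029160 and ENSSTOG00000011297 in every awake library.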

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

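The loess correction, the library weights and the removal of the shared genes were chosen after seeing the data. The 463 calls came to 455 with DESeq2 size factors, 436 with the stricter filter, 525 with robust dispersions, 418 at a change of at least 2-fold, 374 after the loess on abundance and 476 without the shared genes. They came to 230 with upper-quartile scaling and 11 with library totals only, which moved the median log2 fold change of all genes from 0.05 to 0.17 and 0.34. Without a filter there were 766 calls, and the DESeq2 Wald test gave 1618, limma-voom 269 and limma-voom with library weights 908. All 463 genes were among the 1618 of DESeq2. At an adjusted p under 0.01, 1 gene was called. Leaving out 1 library gave 1 to 691 calls. The lowest count came without awake replicate 2 and without awake replicate 3, where 2417 and 2238 genes had an unadjusted p under 0.05 and the 1 gene was among the 463. With 2 libraries in a group, that group's spread is estimated from fewer samples. The other fits that left out 1 library had the same sizes and gave 135 to 691 calls. The number of libraries alone thus did not set the number of calls. As nearly all calls sat close to the threshold, small shifts in p can move their number widely. These counts therefore cannot tell whether a loss of power explains the fall to 1 gene, and its cause was not otherwise tested. No called gene changed direction under any of these alternatives in which it was tested. As 462 of the 463 had no overlap between the groups' libraries, leaving out a library or rescaling could hardly have turned them. The 4 genes with printed identifiers were past the threshold in 10, 11, 9 and 14 of 17 alternatives, in the order in which they were given. Whether replicate numbers pair the samples could not be settled with so few libraries. Deviations of same-numbered libraries correlated at 0.26, -0.21 and 0.14. Hibernating replicates 1 and 3 correlated best with their own number, and replicate 2 with awake replicate 3. A replicate block gave 683 calls, 423 of them among the 463. The planned tests of gene lists and the correction for GC content and length were not run, since no table at hand paired the identifiers with names or sequences. In simulated data only 23.9% of 2-fold changes were recovered at this depth and number of libraries. The simulated groups shared their dispersions and the genes varied independently, so the rate may differ in the real libraries.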

Other observations

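All patterns but the number of calls were noticed in these data. The tests of a single aberrant library and of a source of fixed composition and the loess correction were chosen after related values had been seen, and the other tests before their results were seen. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called as many as 463 genes. The highest of the other splits called 22 and set hibernating replicates 1 and 2 and awake replicate 1 against the rest. With 10 splits the share cannot fall under 0.05.

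A small set of genes was shared by hibernating replicates 1 and 2. Each of 12 genes stood at least 8-fold higher in both of these libraries than in every other library, on the log2 CPM scale with a prior count of 2, and 2 of the 12 were among the 463 calls, ENSSTOG00000026677 being one of them. The set held 0.131% and 0.138% of the counts in the 2 libraries and 0.00289% in hibernating replicate 3, against 0.00188% to 0.00419% in the awake libraries. Any other pair of the 6 libraries shared 0 such genes. The rule leaves out genes that were also raised, to a lesser degree, in another library. Some genes high in hibernating replicates 1 and 2 were also raised in awake replicate 1 and so missed the 8-fold rule. The split that set these libraries against the rest called 22 genes. Genes of this wider pattern were not counted, so the pattern may not be confined to hibernating replicates 1 and 2. RNA of 1 fixed composition, such as another tissue taken along at dissection, would bring all 12 genes into both libraries in 1 ratio. The median log2 ratio of replicate 2 to replicate 1 over the 12 genes was 0.01 with an SD of 0.54, against an SD of 0.70 over 7065 other genes of the same abundance. Counting error alone would give an SD of 0.082 over the 12 genes, so they did not share 1 ratio within it. Other differences between the 2 libraries may also scatter the ratios, as in ordinary genes. The SD was 0.763 of that of ordinary genes, which decides neither way. A carried-over source, sources of differing composition and a difference between animals may each account for the set and remain open, since the genes could not be named.

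The hibernating libraries spread more widely than the awake ones. The common biological coefficient of variation was 0.360 in the hibernating and 0.242 in the awake group, a ratio of 1.48, and the SD was larger in the hibernating group for 64.9% of the tested genes. Depth does not account for it. Library totals already lay close together (16337406 to 19256370 counts), so thinning could move little. After thinning to the smallest of the libraries the ratio averaged 1.495 over 10 draws (1.493 to 1.498). Without the 12 shared genes the ratio was 1.47, but taking 12 of 13850 tested genes out could hardly move it. It was therefore no test of their part. No single hibernating library accounts for all of the spread, since the best hibernating pair still correlated less than the worst awake pair (difference -0.0179). Hibernating replicate 1 may supply part of it. The chi-square per degree of freedom was 112 and 116 for its pairs with hibernating replicates 2 and 3. It was 70.8 between those 2 and at most 48.4 in awake pairs. The coefficient of variation was not computed again without any library. A candidate explanation that the labels leave open is that the hibernating animals were at different stages of a torpor bout when sampled, which may add to variation between them; it was not tested.

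Fold changes fell with abundance, and a biologist would want to know whether this is RNA biology or library composition. Without hibernating replicate 1, the library that contributed most, the contrast between abundance classes 4 and 1 was -0.39, against -0.64 with it. Hibernating replicates 2 and 3 stood at -0.09 and -0.10 on the contrast per library, against 0.13 to 0.43 in the awake libraries. With so few libraries, whether the part that stays exceeds the spread between libraries is not settled. The contrast did not rest on 1 awake library, since the weakest value after leaving one out was -0.572. An even background of reads over all genes is argued against by the 6324 genes with 0 counts in awake replicate 1, whose median gain in hibernating libraries over awake replicates 2 and 3 was 0 CPM, a ratio of 0 to the gain of 0.424 CPM in abundance class 1. A difference in RNA quality, a background that follows gene length, another mix of cells in the dissected nerve and an effect of hibernation all may produce such a gradient and remain open. A loess removes the trend by construction, bringing the contrast from -0.64 to -0.04 and the calls in class 4 from 125 lower and 11 higher to 67 and 28, so it does not bear on the cause. It left 374 calls, 274 of them lower and 313 of them shared with the 463.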
